A study of Homo sapiens with 6 samples.

How the data were processed

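The measurements were read counts of shRNAs in 6 genomic DNA samples of SKK-1 cells, 3 untreated and 3 treated with azacitidine. Per the labels' protocols, each of 3 transduced and puromycin-selected cultures was divided into an untreated and a treated part, DNA was extracted from the harvested cells, and the guide strands were amplified with primers in the vector, cut from a gel at 340 bp and sequenced with a custom primer. Per the submitters' processing notes, CASAVA 1.9 and the GRCh37 assembly were named, without their role. The deposited values were raw counts per shRNA in each sample, per the file headers and the values themselves, which were whole numbers of differing totals. The rule by which reads were matched to shRNAs, and whether mismatches or shifts were allowed, is not given in the sources used here. Primer, amplification and matching choices act before counting, so shRNAs of nearly the same sequence can exchange reads, and duplicates made by the amplification cannot be told from separate cells.

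The files listed an shRNA only where it had at least 1 read, and an shRNA absent from a library was set to 0, which happened in at least 1 library for 38 of 7295 shRNAs. Gene names were taken from the shRNA IDs. In 910 genes 8 shRNAs were listed and in 2 genes 7. The 8 shRNAs of MARCH5 carried a date in the symbol column, as spreadsheet programs produce, and were handled by ID. Of the 912 symbols, 852 are current in the RefSeq gene table and 54 matched through 1 synonym, and 6 did not match or were ambiguous. That table is of another assembly than the one named in the notes, so no coordinates are given. The number that ends an shRNA ID was taken as the position of its target site in the transcript, which the sources used here do not state.

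Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. shRNAs with at least 10 reads in at least 3 libraries were kept, 7266 in all, which left out 29. Library sizes were scaled by TMM, and log2 CPM used a prior count of 2. The main test was the quasi-likelihood test (glmQLFit with robust weighting, glmQLFTest) with treatment and the transduction replicate as terms, since the protocols state that each transduced culture was divided. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. The labels describe 3 transductions of one cell line, so p-values of the quasi-likelihood test measure the spread between these cultures. SEs were obtained from the fold change and the F statistic. Genes with at least 3 tested shRNAs, and 20 gene lists, were tested with camera at a preset correlation of 0.01 against all other shRNAs, two-sided. Its p-values rest on the spread across shRNAs and do not measure that between cultures. The value given for a gene or list is the mean over its shRNAs of the log2 CPM difference between the treated and untreated library of the same number, as mean ± SD over 3 pairs. A member of a list counted as above 0 when that mean was positive.

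The lists covered DNA methylation and demethylation enzymes, methyl-CpG binding proteins, azacitidine metabolism, DNA damage response, Polycomb repressive complexes 1 and 2, SWI/SNF, NuRD, INO80 with SRCAP and TIP60, MLL/SET1, histone deacetylases, acetyltransferases, demethylases and lysine methyltransferases, arginine methyltransferases, bromodomain proteins, cohesin and condensin, histone chaperones, genes mutated in myeloid neoplasms and common essential genes. The design, the lists, the alternatives named as planned and the rule for naming were set before the data were examined. The rule took, in each direction, the 6 shRNAs with the largest fold change among those that passed and went the same way in all 3 pairs, or, where fewer than 3 passed, the 3 with the smallest p; the 10 genes with the smallest camera p in each direction; all DNA methylation and demethylation enzymes; the 2 members of each other list with the smallest p; and the 5 most abundant shRNAs of each group. Other genes and shRNAs named in the text, the neighbours of named shRNAs among them, were chosen after their values were seen. Of the results planned, 2 are not reported here.

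Alternatives were RLE scaling, total counts only, no filter, a filter of at least 50 reads in 3 libraries, no replicate block, no robust weighting, leaving out each replicate number, DESeq2 1.42.0, limma-voom, fry, camera with an estimated correlation, reads summed per gene, and the median against 10000 random sets. Chosen after seeing the data were thinning to the smallest library, summing the reads of overlapping shRNAs (those of one gene with ID numbers at most 3 apart, which turned 7295 shRNAs into 6764), and leaving those shRNAs out. Summing stayed within a gene, so shRNAs shared by near-identical genes such as SMN1 and SMN2 remained separate and are uncertain. Library pairs were compared by a chi-square test of counts, and all differed by far more than sampling noise, so none was treated as a duplicate. The fits were tested on simulated counts with the real means, library sizes and spread, in 5 draws.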

Results

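A pooled knockdown screen asked which chromatin regulators, when their transcripts were lowered, altered how cells fared under azacitidine. Azacitidine is a cytidine analogue used in myeloid neoplasms that is built into nucleic acids and traps DNA methyltransferases. SKK-1, which the labels describe as a cell line of acute myeloid leukaemia, received the Epi9 library of short hairpin RNAs (shRNAs) in 3 separate transductions. Per the labels' protocols the library held 7296 shRNAs against 912 genes. After puromycin selection each transduced culture was divided into an untreated part and a part given 0.075 µM azacitidine every 2 days for 2 weeks. On day 21 the integrated shRNA guide strands were amplified from genomic DNA and counted by sequencing. A larger share of reads for an shRNA was therefore read as a larger share of cells carrying it. This reading is uncertain where shRNAs of nearly the same sequence can exchange reads.

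The 6 libraries, 3 untreated and 3 treated, listed 7295 different shRNAs, and 912 genes were targeted. Untreated libraries 1, 2 and 3 held 19700333, 122293871 and 23775842 reads, and treated libraries 1, 2 and 3 held 23721681, 28355723 and 27935583. Each library listed between 7276 and 7286 shRNAs, with a median of 1273 to 11422 reads per shRNA. Depth was therefore ample, yet libraries of one group resembled each other only loosely. Across shRNAs, which are not independent replicates, Pearson's r of log2 CPM (reads scaled to a common library size) lay between 0.42 and 0.54 for pairs of untreated libraries and between 0.43 and 0.54 for pairs of treated libraries. For an untreated with a treated library it lay between 0.41 and 0.60, so pairs across the groups were no less alike. The common biological coefficient of variation of the edgeR fit was 0.778. For the 1013 tested shRNAs with another shRNA of the same gene at most 3 positions away by ID number, the median SD of log2 CPM over the 6 libraries was 1.73, against 0.976 for the 6253 without such a neighbour.

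At the level of single shRNAs, those with the smallest p among the higher ones in treated cells were CDK17.1342, UBE2A.568 and CBX2.164, and among the lower ones PARP12.1718, ADPRH.2435 and CBX2.162; none of these 6 passed adjusted p 0.05. CDK17 encodes a cyclin-dependent kinase, UBE2A a ubiquitin-conjugating enzyme acting in post-replication repair, CBX2 a Polycomb chromodomain protein, PARP12 an ADP-ribosyltransferase and ADPRH an ADP-ribosyl hydrolase. CDK17.1342 stood at 8.77 ± 2.86 CPM (SD, n = 3) untreated and 586 ± 50.2 CPM treated, a log2 fold change of 6.10 (SE 0.81, edgeR quasi-likelihood test, adjusted p = 0.0546), and was higher in 3 of 3 pairs. Its neighbour CDK17.1341, 1 position away, went the other way, from 873 ± 275 to 200.2 ± 217 CPM, and the summed reads of both stood at 882 ± 279 and 787 ± 264 CPM. For the sum the log2 fold change was −0.17 (SE 0.56, adjusted p = 0.999). CBX2.164, at log2 5.05, and CBX2.162, at log2 −4.40, lie 2 positions apart, and their sum had a log2 fold change of −1.03 (SE 0.81, adjusted p = 0.999). PARP12.1718, at log2 −4.47, had the neighbour PARP12.1719 at log2 2.80, and the sum gave −1.01 (SE 0.61). ADPRH.2435, at log2 −4.44, had the neighbour ADPRH.2436 at log2 1.24, and the sum gave −0.42 (SE 0.60). UBE2A.568, at log2 3.18, had the neighbours UBE2A.569, at log2 1.09 in the same direction, and UBE2A.570, at log2 −1.61. The sum of these 3 shRNAs gave −0.04 (SE 0.57). All 6 shRNAs that the rule named thus had such a neighbour, which 13.9% of the tested shRNAs had.

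**Figure D1:**
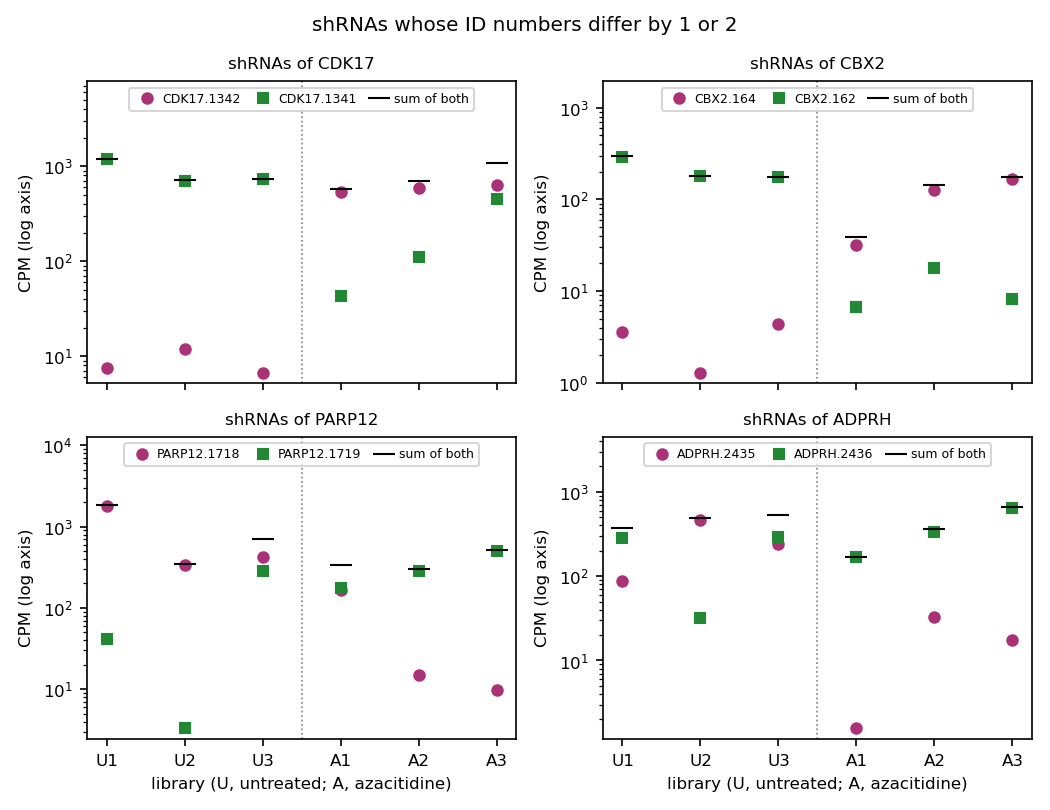
Reads per library, in CPM on a log axis, of 4 named shRNAs (circles), of the overlapping shRNA of the same gene (squares) and of their sum (dashes), for the 3 untreated and 3 azacitidine libraries. CDK17.1342 lies at 8.77 CPM on average in the untreated and 532 to 632 CPM in the treated libraries, while the CDK17 sum lies at 708 to 1204 CPM in the untreated and 573 to 1082 CPM in the treated ones.

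Over all 7266 tested shRNAs, 0 passed adjusted p 0.05 in the edgeR test with the transduction as a block. At unadjusted p under 0.05 there were 102 higher and 72 lower, where chance alone would give 363.3. DESeq2 called 71 shRNAs and limma-voom 3; when the reads of overlapping shRNAs were summed, DESeq2 called 23. Of the 71 DESeq2 calls, 46 (64.8%) had an overlapping neighbour (Fisher's exact test against the other tested shRNAs, two-sided p = 5.27e-23). In counts simulated with this spread, the edgeR test recovered 0% of 2-fold, 2.8% of 4-fold, 16.4% of 8-fold and 48% of 16-fold changes of single shRNAs. Most changes of 8-fold or less were thus missed in such counts. The simulated shRNAs were independent of each other, so recovery in the real libraries may differ.

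Taking all shRNAs of a gene together, the 5 genes with the smallest camera p among the higher ones included FBXO11, a substrate receptor of an SCF ubiquitin ligase, and ASH2L and DPY30, both core subunits of the MLL/SET1 histone methyltransferases. Cells carrying shRNAs against FBXO11 had a mean log2 ratio of treated over untreated reads of 1.30 ± 0.42 (SD, n = 3 pairs), with 8 of 8 shRNAs higher. For ASH2L the ratio was 1.04 ± 0.45, also with 8 of 8 shRNAs higher, and for DPY30 it was 0.96 ± 0.99. Among the lower ones the 4 smallest p belonged to BAZ1A, the bromodomain subunit of the ACF remodeller (−1.02 ± 1.06), TADA2A, an adaptor of histone acetyltransferase complexes (−0.93 ± 0.48), the acetyltransferase CREBBP (−0.80 ± 0.88) and PARP2, a poly(ADP-ribose) polymerase acting in DNA repair (−0.84 ± 0.20). None of the 912 genes passed adjusted p 0.05 in the camera test, whose smallest adjusted p was 0.462. At unadjusted p under 0.05 there were 26 higher and 21 lower genes, where chance would give 45.6. With overlapping shRNAs summed there were 34 higher and 28 lower, and 60 in all with those shRNAs left out; whether these counts exceed chance was not tested. Fry, camera with an estimated correlation and the median against random sets also called 0. Of these, camera with an estimated correlation gave 0 genes even at unadjusted p under 0.05, so it could hardly call any. The edgeR test on reads summed per gene called 2 genes, ASH2L and FBXO11 (adjusted p = 0.0291 for each).

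The other genes named as higher were FLYWCH1, a zinc finger protein (1.49 ± 0.48), NAA15, the auxiliary subunit of an N-terminal acetyltransferase (1.02 ± 0.88), PHF12, a SIN3-associated PHD finger protein (1.00 ± 0.60), the splicing helicase DDX46 (1.20 ± 0.76), the CpG island-binding F-box protein FBXL19 (1.12 ± 1.14), the excision repair helicase ERCC2 (0.97 ± 0.08) and the histone methyltransferase EHMT2 (0.95 ± 0.65). Those named as lower were WDR82, a subunit of the SET1 complexes (−0.97 ± 0.80), the methyl-CpG binding protein MBD2 (−1.05 ± 1.16), the replicative helicase subunit MCM7 (−1.20 ± 0.06), the remodeller CHD2 (−0.88 ± 0.71), the NuRD subunit MTA2 (−0.85 ± 0.39) and the F-box protein FBXO10 (−0.79 ± 0.73). Adjusted p lay between 0.462 and 0.859 for these 20 genes. For BAZ1A, CREBBP, FBXL19 and FBXO10 the 3 pairs did not all go the same way. Pair 3 was the one that differed for the first 3 of these, at 0.18, 0.21 and −0.08. Pair 1 held the value furthest from 0 for all 20 genes except ERCC2, CREBBP and FBXO10. The cause was not tested. When overlapping shRNAs were summed, MCM7 moved to −0.45 ± 0.50 and its adjusted p to 0.923. FBXL19 moved to 0.84 ± 1.13 and FBXO10 to −0.54 ± 0.55, with unadjusted camera p of 0.0607 and 0.0783. FLYWCH1 stood at 1.31 ± 0.70, CHD2 at −0.97 ± 0.77 and FBXO11 at 1.21 ± 0.17, the last with an adjusted p of 0.0927. In simulated counts, 25% of genes with all shRNAs changed 2-fold and 95% of those changed 4-fold were recovered. These counts held no opposed neighbours and 1 fold change for all shRNAs of a gene, so recovery in the real libraries may differ.

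**Figure D2:**
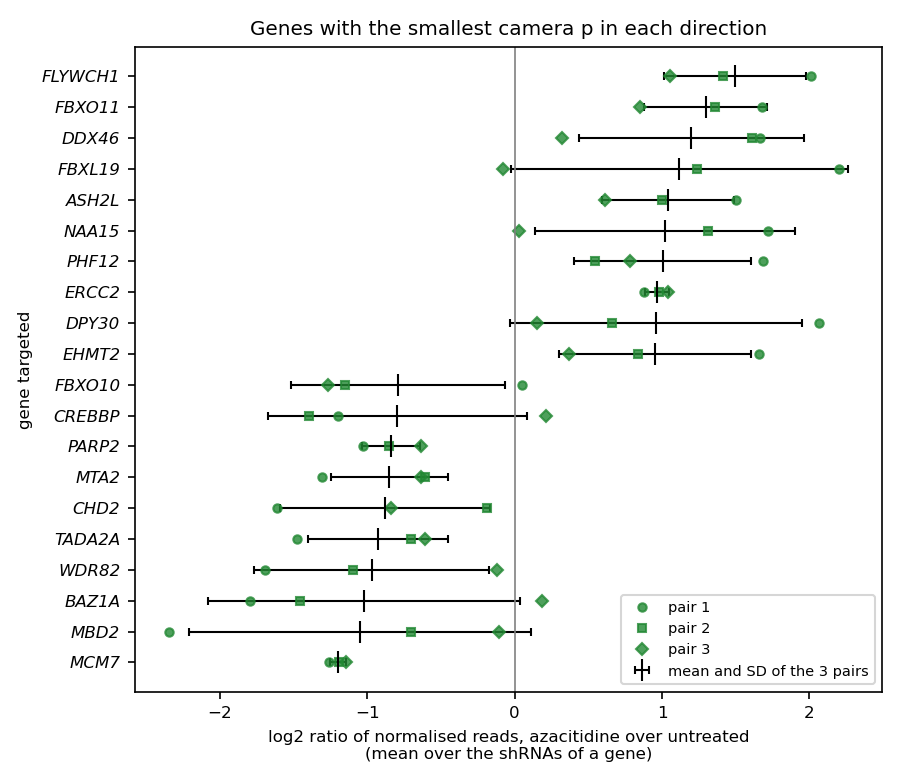
Mean log2 ratio of normalised reads, azacitidine over untreated, over the shRNAs of each named gene, for each of the 3 transductions (green symbols) with the mean and SD of the pairs (black). Means run from 0.95 to 1.49 for the 10 genes named as higher and from −1.20 to −0.79 for the 10 named as lower, and no gene passed the adjusted threshold.

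Among the gene lists fixed beforehand, the DNA methylation and demethylation enzymes, which include the targets of azacitidine, gave 0 calls among 10 genes over all genes tested and 0 adjusted over the list alone. DNMT1, the maintenance methyltransferase, had a log2 ratio of −0.33 ± 1.04 (SD, n = 3 pairs), DNMT3A 0.04 ± 1.40 and DNMT3B −0.48 ± 0.40, with DNMT3B lower in 3 of 3 pairs. The dioxygenases TET1, TET2 and TET3 stood at −0.13 ± 0.25, 0.23 ± 0.50 and −0.18 ± 0.37. The hemimethylated DNA readers UHRF1 and UHRF2 stood at −0.09 ± 0.93 and 0.35 ± 0.71, the RNA methyltransferase TRDMT1 at 0.37 ± 0.65, and the inactive cofactor DNMT3L at 0.34 ± 0.31, or 0.07 ± 0.30 with overlapping shRNAs summed. The list's adjusted camera p was 0.891. The only measured member of the list of azacitidine uptake, activation and breakdown was CDA, cytidine deaminase. It stood at 0.51 ± 0.24 and was higher in 3 of 3 pairs, with an adjusted camera p of 0.891 as a list.

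The MLL/SET1 complexes ranked first among the lists by camera, at an adjusted p of 0.891, with 14 of 20 genes above 0 and a mean log2 ratio of 0.27 ± 0.24 (SD, n = 3 pairs). Adjusted over the list alone, 3 members passed, ASH2L and DPY30 as higher and WDR82 as lower (adjusted p = 0.0450 at the smallest), against 0 over all genes tested. Of single shRNAs in this list DESeq2 called DPY30.396 and RBBP5.1059 as higher, also with overlapping shRNAs summed. FBXO11 passed adjusted over the list alone among the protein arginine methyltransferases (adjusted p = 0.00934), where 9 of 11 genes lay above 0, the list's adjusted camera p was 0.891 and CARM1 stood at −0.51 ± 1.13. FBXO11 was placed there for a reported methyltransferase activity, but is best known as a ubiquitin ligase subunit. BAZ1A passed in the same way among bromodomain proteins (adjusted p = 0.0322), a list with 18 of 31 genes above 0, an adjusted camera p of 0.891 and BAZ2A at 1.08 ± 0.15. In each other list 0 members passed adjusted over the list alone. These passes were obtained with the preset correlation of 0.01. With an estimated one 0 of 912 genes had even an unadjusted p under 0.05, where chance would give 45.6. That variant could hardly call any gene, so whether the passes depend on the preset value cannot be told from it. The 20 lists had adjusted p from 0.891 to 0.908 with the preset correlation and from 0.764 to 0.875 with an estimated one, so 0 lists passed, and 0 had a camera p under 0.05. Fry also called 0, with its smallest adjusted p = 0.0627 at the histone demethylases.

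Repressive complexes held no gene called by camera. At the level of single shRNAs DESeq2 called some of their members, JARID2.231, AEBP2.1566 and BMI1.2871 among them also with overlapping shRNAs summed. DESeq2 also called COMMD3-BMI1.895 there, at log2 −3.24 beside −3.77 for BMI1.2871. Summing stayed within a gene, so reads shared between BMI1 and COMMD3-BMI1 were not tested. In Polycomb repressive complex 1, with 11 of 21 genes above 0, PCGF1 stood at −0.73 ± 0.40 and CBX7 at −0.81 ± 1.48. In Polycomb repressive complex 2, with 8 of 12 genes above 0, JARID2 stood at 0.91 ± 0.29 and EZH1 at −0.48 ± 0.24, the latter at −0.24 ± 0.17 with overlapping shRNAs summed. NuRD, with 6 of 14 genes above 0, held MBD2 and MTA2, and the methyl-CpG binding proteins, with 4 of 8 genes above 0, MBD2. Histone deacetylases and corepressors had 19 of 32 genes above 0, with HDAC9 at 0.92 ± 1.20 and HDAC10 at −0.93 ± 0.59, or −0.59 ± 0.59 with overlapping shRNAs summed. Lysine methyltransferases outside MLL/SET1 had 20 of 31 genes above 0, with EHMT2 named above and SETD4 at −0.61 ± 0.80.

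Activating and remodelling groups also held 0 genes called by camera. Of the histone acetyltransferases 13 of 25 lay above 0, with CREBBP named above and PHF17, now called JADE1, at 1.00 ± 0.87. Of the histone demethylases 20 of 26 lay above 0, with JMJD1C at 0.91 ± 0.85 and KDM8 at 0.76 ± 0.09. SWI/SNF had 16 of 21 genes above 0, with ARID1A at 0.81 ± 0.74 and ACTL6A at −0.64 ± 1.22, and the INO80, SRCAP and TIP60 complexes had 17 of 28, with RUVBL1 at 0.65 ± 0.61 and INO80B at 0.44 ± 0.47. DNA damage response and repair had 11 of 24 genes above 0, with PARP2 named above and the glycosylase TDG at −0.50 ± 0.43. Histone chaperones had 8 of 15 above 0, with ATRX at −0.74 ± 0.28, or −0.41 ± 0.57 with overlapping shRNAs summed, and DAXX at −0.35 ± 0.13. Of cohesin and condensin 2 genes were measured, ESCO1 at 0.40 ± 0.37 and ESCO2 at −0.28 ± 0.51. Genes mutated in myeloid neoplasms had 13 of 21 above 0, with CREBBP and ASXL2 (−0.56 ± 0.43) at the smallest p. Camera compares a list with all other shRNAs, and the mean log2 ratio of all tested shRNAs was 0.08. Its direction was lower for the bromodomain proteins, histone chaperones, acetyltransferases, DNA damage response, myeloid and common essential lists, cohesin and the DNA methylation enzymes, although their mean log2 ratio lay above 0, and for NuRD although its median shRNA, at 0.05, lay above 0. For the common essential list the mean, 0.09, was not below that of all shRNAs, so the shift of all shRNAs does not account for its direction.

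The most abundant shRNAs of untreated cells included 3 against CREBBP. CREBBP.1135, CREBBP.3254 and CREBBP.2034 took 0.270 ± 0.028%, 0.237 ± 0.026% and 0.186 ± 0.005% of reads (SD, n = 3), and none had an overlapping neighbour. DDX39B.221 took 0.159 ± 0.019%, and its neighbour DDX39B.222, 1 position away, stood at 69.5 ± 58.7 CPM untreated and 740 ± 563 CPM treated, against 1677 ± 398 and 670 ± 978 CPM for DDX39B.221. In pair 3 DDX39B.221 was higher in the treated library, at 1798 against 1284 CPM, unlike in pairs 1 and 2. The CREBBP shRNAs took 0.027% to 0.059% in treated libraries 1 and 2, but 0.162% to 0.193% in treated library 3. The most abundant of treated cells included AKAP8.2525 (0.152 ± 0.098%), ING1.1659 (0.121 ± 0.041%), ASH2L.389 (0.115 ± 0.055%) and NAA15.1242 (0.102 ± 0.050%).

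**Figure D3:**
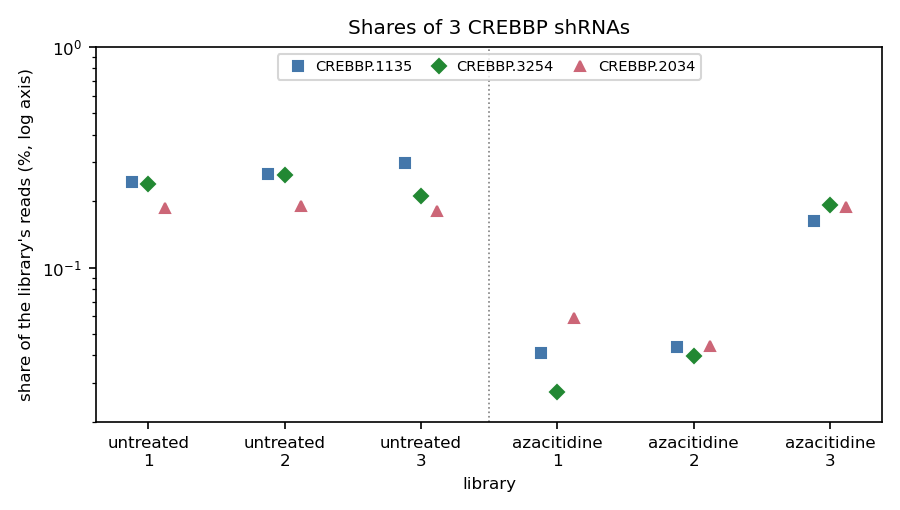
Share of each library's reads, in percent on a log axis, taken by 3 shRNAs against CREBBP in the 3 untreated and 3 azacitidine libraries. They lie at 0.027% to 0.059% in treated libraries 1 and 2 and at 0.162% to 0.193% in treated library 3, lower in treated libraries 1 and 2 than in the untreated ones.

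In untreated cells, shRNAs against common essential genes were less abundant than those against other genes. The median over the 30 measured genes of this list was 5.48 log2 CPM, against 6.22 for the other genes, a difference of −0.74 ± 0.20 (SD over 3 untreated libraries), and 0 of 10000 random lists of the same size were as low. Of the 91 least abundant genes, 9 were on the list, where chance would give 2.99 (Fisher's exact test, two-sided p = 0.00162). WDR5 and HCFC1, both MLL/SET1 partners, the NuRD helicase CHD4, the acetyltransferase KAT8 and the methyltransferase PRMT1 stood among the lowest, at 4.06 ± 0.78, 4.12 ± 0.12, 4.15 ± 0.86, 4.20 ± 0.93 and 4.31 ± 1.01 log2 CPM (SD, n = 3). A sample from before the culture was not analysed here, so these values hold the starting library as well as the growth of the cells. Under azacitidine the list as a whole gave an adjusted camera p of 0.891, with a mean log2 ratio of 0.09 ± 0.22 (SD, n = 3 pairs) and 17 of 30 genes above 0, and its members with the smallest p were ACTL6A and AURKB (−0.64 ± 0.95, or −0.37 ± 1.14 with overlapping shRNAs summed).

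**Figure D4:**
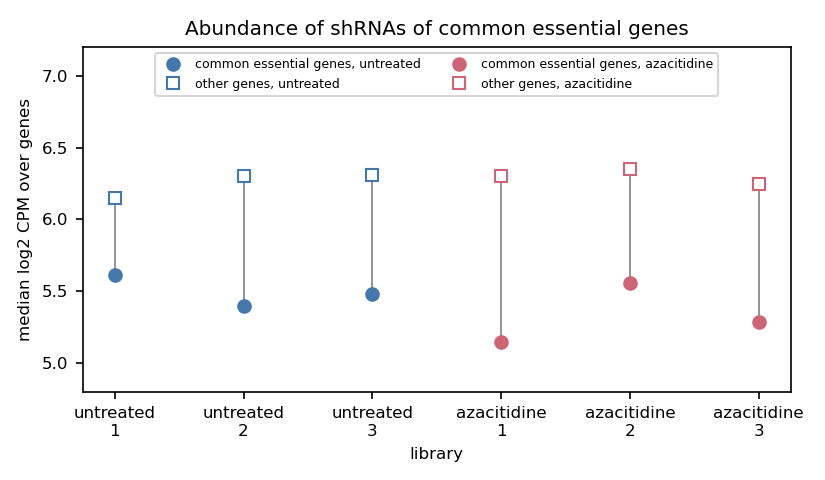
Median log2 CPM over the 30 common essential genes (filled circles) and over all other genes (open squares) in each of the 6 libraries, where a gene's value is the mean over its shRNAs. The common essential genes lie below the others in every library, by 0.53 to 0.90 in the untreated and 0.79 to 1.15 in the treated ones.

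Treated populations were not measurably more skewed than untreated ones. The Gini index of reads over shRNAs was 0.538 ± 0.070 (SD, n = 3) untreated and 0.498 ± 0.053 treated (exact sign-flip permutation test of the 3 pairs, two-sided p = 0.75). It was highest in untreated library 1, at 0.617, which also had the fewest reads, and lay between 0.467 and 0.559 in the other libraries. The 10 most abundant shRNAs took 3.49 ± 1.62% and 1.88 ± 0.67% of reads and the 100 most abundant 10.7 ± 0.81% and 8.93 ± 1.38%, both lower under azacitidine in 3 of 3 pairs (exact sign-flip permutation p = 0.25 for each). With 3 pairs this test cannot go below 0.25, and the unpaired permutation test, which gave 0.2 for each, cannot go below 0.1. The number of shRNAs detected was 7281 ± 5 untreated and 7278.7 ± 2.5 treated, with at least 10 reads for 7242 ± 23 and 7248 ± 6.5 shRNAs.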

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

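Thinning and summing or leaving out overlapping shRNAs were chosen after seeing the data. The count of shRNAs past adjusted p 0.05 was 0 and stayed 0 with RLE scaling, with no filter, with at least 50 reads, when thinned, and with overlapping shRNAs summed or left out. It was 1 (CDK17.1342) with total counts only, with no replicate block and with no robust weighting, 0 to 4 when a replicate was left out, 3 with limma-voom, 71 (42 higher, 29 lower) with DESeq2 and 23 with DESeq2 after summing, of which 22 were among the 71. The cause of these differences between tools was not tested. Without replicate 1 the 3 were CDK17.1342, SIN3B.520 and an shRNA against CDY2A, and without replicate 3 the 4 included CDK17.1342, CREBBP.3254 and DDX39B.221. Total counts only moved the median log2 fold change of all shRNAs from 0.03 to 0.15, the largest shift among the scalings. Genes past the threshold were 0 under each alternative except reads summed per gene, which gave 2, and lists were 0 under each. The robust setting does not enter camera, so it gives no gene or list value. For the 54 named genes, 624 of 648 alternative values stayed within 1 SD of the reported value, 22 moved further, 2 crossed the threshold and 12 had the other sign. For the 6 named shRNAs, 55 of 66 values stayed on the same side of the threshold and 11 crossed it, with 0 changes of sign. These values leave out the summing of overlapping shRNAs. The sums that hold CDK17.1342 (−0.17), UBE2A.568 (−0.04) and CBX2.164 (−1.03) had the other sign than these shRNAs. The sums that hold PARP12.1718, ADPRH.2435 and CBX2.162 kept the sign.

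As to pairing, libraries of the same number did not deviate together from their group means (r −0.04, 0.05 and −0.08, mean −0.03), nor did libraries of different numbers (mean 0.01), so the block rests on the protocol and not on the data; without it the counts were 1 shRNA, 0 genes and 0 lists. Depth is not the limit, since the reads of the shallowest library, divided at random into equal parts, correlated at 0.997.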

Other observations

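Tests chosen only after the result was seen are those of a transduction bottleneck, of read exchange in each single library, and the splits for shRNAs and genes past the adjusted threshold. Among untreated cells CREBBP, a histone acetyltransferase, had the most abundant shRNAs, at 9.09 ± 0.22 log2 CPM as a mean over its shRNAs (SD, n = 3), which is 2.90 above the median gene, and it ranked at 909 or higher of 912 genes in each of the 6 libraries. ZHX1, a zinc finger and homeobox repressor, stood at 8.23 ± 0.13, CHRAC1, a histone-fold remodelling subunit, at 7.96 ± 0.18, the helicase DHX40 at 7.94 ± 0.19 and the SAGA subunit ENY2 at 7.90 ± 0.22. At the other end were FLYWCH1 (3.98 ± 0.74), FBXL19 (4.05 ± 0.33), the ubiquitin ligase adaptor DDB1 (4.16 ± 0.31), the ubiquitin-activating enzyme UBA1 (4.17 ± 0.40), the single-strand DNA-binding protein RPA1 (4.38 ± 0.87), the MLL partner MEN1 (4.49 ± 0.17) and the haematopoietic transcription factor MYB (4.57 ± 0.66). FLYWCH1 and FBXL19, the least abundant by this mean, were also among the 10 genes named as higher under azacitidine, and CREBBP, the most abundant, among those named as lower. Of the others named as higher, DDX46, PHF12, EHMT2 and ERCC2 ranked 12, 27, 44 and 74 from the lowest. FBXO11, ASH2L, NAA15 and DPY30 were more abundant than these. In the MLL/SET1 list WDR5, HCFC1, CXXC1 and MLL4, with ratios above 0, ranked 3, 4, 19 and 36, and MEN1, below 0, ranked 17. This comparison was chosen after the values were seen, and the log2 ratio holds the same untreated values. Noise in those values alone would make genes low in untreated cells appear higher under azacitidine, and abundant ones lower.

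The hypothesis that shRNAs of one gene share a level of abundance was tested by permuting gene labels over shRNAs. The variance of gene means in untreated cells was 1.81 times that of permuted labels (one-sided permutation p = 1e-05, the smallest that 100000 permutations can give), as the hypothesis requires, in one direction that includes both growth and the starting library. The same test of the log2 fold changes under azacitidine gave 1.05 (permutation p = 0.130). The bound set beforehand, any p of 0.05 or more, was a poor one, since a missed threshold excludes no shift and opposed neighbours cancel within a gene. With overlapping shRNAs summed, the ratio was 1.21 (permutation p = 1e-05, again the smallest possible), so shRNAs of one gene may shift together more than chance allows, although no single gene passed. Whether this shift belongs to azacitidine stays open. With plain differences of log2 CPM, the real split gave a ratio of 1.16 and the highest of the other splits 1.15, and 1 of 10 splits, the real one, was as large, which is too few splits for a share under 0.05.

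Neighbouring shRNAs of one gene went in opposite directions. In 552 pairs of shRNAs with ID numbers at most 3 apart, from 391 genes, log2 fold changes correlated at r = −0.354 across pairs (permutation p = 1e-05, the smallest possible), with 344 pairs (62.3%) of opposite sign, against r = 0.023 and 49.6% for 23420 pairs over 50 apart. The correlation was −0.38 at 1 apart, −0.36 at 2, −0.15 at 3 and 0.05 at 4 to 6. A response set by the target site predicts a positive correlation, so by itself it does not explain that −0.354. Whether such a response is also present cannot be told, since exchanged reads would oppose neighbours whatever the response. Reads passed between overlapping sequences are a candidate explanation. Its bound of r under −0.2 was met, but restates the pattern and is no separate test. This explanation also predicts that neighbours oppose each other within each group, which held in 6 of 6 libraries (r −0.43 to −0.31). Those deviations were taken from the mean of the own group, so they hold no difference between the groups. Sums of neighbours had a median within-group SD of 0.662 log2 CPM, below the 0.918 to 1.02 of 100 random re-pairings of the same shRNAs but no lower than sums of as many random shRNAs of one gene without a neighbour (0.636 to 0.721), while the step at which reads could be exchanged, in matching or amplification, was not tested.

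Libraries of one group agreed loosely (mean r 0.475). Read sampling is excluded, since the reads of the shallowest library, divided at random into equal parts, correlated at 0.997, and so are a few very abundant shRNAs, since r without the 100 most abundant was 0.456. A bottleneck at transduction is argued against by the deviations of same-numbered libraries (mean r −0.026), and whichever numbers belong together, no untreated and treated library deviated together at more than 0.099. Overlapping shRNAs account for a part at most, since within-group r was 0.280 for shRNAs with a neighbour and still only 0.530 for those without. Losses after the cultures were divided, in culture or in the DNA put into amplification, stay open and untested.

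Fewer cell divisions under azacitidine could leave depleted shRNAs less depleted, so that genes low in untreated cells gain. To avoid shared noise, the log2 ratio of 2 pairs was set against the untreated library of the pair left out. Across genes, which are not independent replicates, r was 0.004, −0.072 and −0.207 for pairs 1, 2 and 3 left out, with a mean of −0.0917, between the bound of −0.1 that the hypothesis needs and the −0.05 that would argue against it. For the common essential list the camera p was 0.815 unadjusted and 0.891 adjusted, but a missed threshold, which had been set as the bound, excludes nothing, so the hypothesis is undecided.

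Splits of the 6 libraries into 3 and 3 number 10, the real one included, too few for a share under 0.05. For shRNAs past adjusted p 0.05 the real count was 0 and the highest other 0, so all 10 were as large, and at unadjusted p under 0.05 it was 174 against 1000, with 7 of 10 as large. Splits that leave 2 pairs undivided estimate the difference from 1 pair, which is where the 1000 arose. Each of them compares treated with untreated cells of that pair. Those that part the same pair repeat 1 test with the sign turned, at 1000 shRNAs for pair 1, 153 for pair 2 and 262 for pair 3. The shares of 10 given here count these repeats, so they draw no line between the real split and the others. Among the other splits that part all 3 pairs the counts were 172, 237 and 463, beside the real 174. For genes the adjusted count was 0 against 1, with 10 of 10 as large, and the unadjusted count 47 against 45, with 1 of 10, the real one, as large. For lists past the threshold the count was 0 in all 10.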
